A study of Ovis aries with 8 samples.

How the data were processed

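Gene expression was measured in 8 hypothalami of fetal sheep, 1 array per fetus, with an Agilent sheep expression microarray of 15008 probes. According to the labels, 4 fetuses had estradiol-3-sulphate infused into the lateral cerebral ventricle at 1 mg per day from an osmotic mini-pump, and 4 co-twins served as controls. The labels differ on 2 points. The infusion is given as 7 to 12 days in the design text and as 7 to 10 days in the treatment protocol, and the controls are called untreated in the first and infused with saline vehicle in the second. Surgery was at 120 to 127 days of gestation and tissue was taken at 130 to 134 days. Per the labels' protocols, RNA had been stored for 7 years before 1 µg was labelled with Cy3. The labelled RNA carried 10.41 to 19.73 pmol of dye per µg, and 5.0 to 12.8 µg of it was obtained.

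Per the file headers, spot intensity was extracted from a 1-colour scan with Agilent Feature Extraction 10.1.1.1. The deposited processed intensity is background-subtracted with spatial and multiplicative detrending within each array, per the file headers, and is not normalized between arrays. Values near background are replaced there by a surrogate. The authors also deposited a table of log2 values. Set against the scanner files, each of its columns is log2 of the processed intensity minus 1 constant per array for at least 99.667% of probes, within 0.001. Column medians ran from 0.0576 to 0.075, so the scale and the direction are known, while the rule behind the constant is not given in the sources used here. This table held 18 blank values and was used only as an alternative. All 8 arrays lay on 1 slide with 1 scan time, so neither could be a batch. The treated fetuses occupied the first column of the slide and the controls the second, so slide column and treatment cannot be told apart.

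From the scanner files, control spots and spots with an outlier flag were left out, spots of a probe were averaged, and log2 processed intensity was expressed relative to the 75th percentile of each array. Probes flagged as well above background on at least 4 of the 8 arrays were kept, which left 11749 and removed 3259. Between 67.8% and 83.1% of probes were well above background per array, and no probe was saturated. For arrays, precision is limited by their number, here 4 per group. No 2 arrays held identical values, and correlations between arrays ran from 0.972 to 0.991 within groups. Each fetus counted as a replicate.

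Probe names came from the array design. They were updated through a RefSeq gene table of the assembly ARS-UI_Ramb_v3.0, used for names alone, so no coordinates are given. A name was found for 1693 probes (11.3%), giving 1034 gene names, of which 580 had more than 1 probe. Of the named probes, 703 were matched by RefSeq accession, 515 by symbol, 125 by gene number, 26 by synonym, 122 were read from the design's description and 202 kept the design's own name. The other 13315 probes on the array had no name, and those of them that passed the filter were tested without one. For a gene with several probes, the probe with the highest mean signal over all arrays stands for it.

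Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. All p-values of single genes below come from this model. The labels do not say that equal replicate numbers mark co-twins, so the number was not used in the model. Differences are estradiol sulphate minus vehicle on the log2 scale. For a probe not well above background on any array of a group, its fold is given only as a bound. A log2 difference given for such a probe is set in part by background. For the bound, the mean of the brighter group is set against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background.

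Before the data were examined, 30 gene lists, the model and the rule for named genes were fixed. The rule takes 26 key genes wherever the array names them, which held for 18, and the 12 largest rises and falls past the adjusted threshold. Where fewer passed, it fills each direction to 12 by the smallest unadjusted p and gives these as values that did not pass. It adds 2 to 4 members of each list described, those with the smallest p. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01 against all other genes and unnamed probes, adjusted over the 24 lists tested. The tested lists were hypothalamic neuropeptides, appetite and energy balance, the stress axis, the reproductive axis, oestrogen-responsive genes, steroid sulphate handling, prostaglandins, GABA and glutamate signalling, monoamine and acetylcholine signalling, immediate early genes, hypoxia and glycolysis, ribosomal proteins, the proteasome, heat shock, the cell cycle, inflammation, interferon response, apoptosis, and markers of astrocytes, microglia, endothelium, meningeal matrix, erythroid cells and the pituitary. The other 6 lists had too few measured genes.

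Both procedures were tested on simulated data for this comparison, without correlation between genes. The data were drawn from the means of 11735 probes and their moderated variances, which limma draws towards a common value. These variances differ less between probes than the probes' own, so recovery in real data may differ. Of 200 changed probes, 50 at each size, the model recovered 2.0% at a log2 change of 0.5, 80.0% at 1, 88.0% at 1.5 and 96.0% at 2, with 7 false calls among 140. With 14 genes of the GABA and glutamate list raised by 0.3, camera called the list in 20 of 20 runs, and 3 of 480 tests of unchanged lists were called. These runs hold no correlation between genes, so they do not show how often correlated lists are called by chance.

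Alternatives covered the normalization (quantile, normexp with an offset of 50 on mean and background intensity followed by quantile, median scaling over probes above background on all arrays, the deposited log2 table), the filter, the replicate number as a fixed or random block, array weights, a trended robust prior (for camera the trend alone, since it has no robust option), the summary of probes, camera with an estimated correlation, fry (which tests a list against no change, not against other genes), and leaving out each array. Cyclic loess normalization was added after seeing the data.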

Results

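The series holds 8 hypothalami from late-gestation sheep fetuses of 4 twin sets, 4 infused with estradiol-3-sulphate and 4 controls called vehicle here. Estradiol-3-sulphate is the sulphate conjugate of estradiol, which steroid sulphatase can turn back into the active hormone. The infused fetuses gave brighter arrays. The 75th percentile of processed intensity was 1690, 2038, 2251 and 1584 in estradiol sulphate replicates 1 to 4, and 1609, 1479, 1297 and 969 in vehicle replicates 1 to 4. The share of probes well above background was 77.0% to 83.1% in the first group and 67.8% to 77.4% in the second. Vehicle replicate 4 had the lowest signal and lay apart on the first principal component, which held 32.9% of the variance.

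The comparison of the groups asks which transcripts of the fetal hypothalamus differ after the infusion. Neither of the appetite peptide genes *NPY* and *AGRP* passed after adjustment. *NPY*, which stimulates feeding, was 3.05-fold brighter after estradiol sulphate. *AGRP*, which antagonises melanocortin receptors, was 12.7-fold brighter, with 2 of 4 control fetuses not well above background and a log2 difference of 3.66 that ran from 2.62 to 4.74 over the alternatives, the highest without vehicle replicate 1. As lists, genes of appetite and energy balance and genes of GABA and glutamate signalling were shifted upwards, and ribosomal protein genes downwards, at camera's preset correlation. All 3 calls are lost with an estimated correlation (adjusted p = 0.442). No single probe of the 11749 passed the adjusted threshold in limma. The smallest adjusted p was 0.240, and *LEF1* was among the probes with this value.

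At an unadjusted p under 0.05, 733 probes were higher and 344 lower after estradiol sulphate, 1077 in all against 587 expected by chance. The split depended on the scaling and the filter. It was 396 higher and 297 lower with quantile normalization, 422 and 329 with normexp and quantile, and 448 and 338 with cyclic loess. It was 539 and 493 with median scaling. It turned to 904 higher and 1186 lower with no filter on dim probes, and with the authors' deposited log2 values to 344 higher and 760 lower, because their centring moves the median difference over all probes by -0.10, from 0.04 to -0.06. Without vehicle replicate 2 there were 474 higher probes, and without estradiol sulphate replicate 2 there were 178 lower ones. The groups did not overlap in 386 higher and 315 lower probes, where chance gives 336 in all on average (2.86%). Both chance numbers are averages, and single counts can lie far from them. Over other splits of the same arrays into equal groups, probes at an unadjusted p under 0.05 numbered 130 to 1303. Chance can therefore not be excluded for the 1077. The count of probes without overlap was not compared over such splits.

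The appetite and energy balance list had 12 measured genes, 11 above 0, with a median difference of 0.33 (camera, adjusted p = 0.00930), a call lost with an estimated correlation (adjusted p = 0.442). No member passed over all probes, and 3 passed when adjusted over the list alone, namely *NPY*, *AGRP* and *FTO*. *NPY* averaged 1.44 ± 0.69 (SD, n = 4) against -0.16 ± 0.75 (SD, n = 4), all log2 relative to the array's 75th percentile, a difference of 1.61 ± 0.42 (SE; limma adjusted p = 0.427). All 4 treated fetuses lay above every control. *AGRP* averaged -0.12 ± 1.41 (SD, n = 4) against -3.78 ± 2.33 (SD, n = 4), a difference of 3.66 (limma adjusted p = 0.437). It was well above background in 4 treated and 2 control fetuses, and 3 treated fetuses exceeded every control. *FTO*, the demethylase gene linked to body weight, differed by 0.63 ± 0.14 (SE; adjusted p = 0.372), and its other probe by 0.64. The orexin receptor gene *HCRTR2* differed by 0.36 ± 0.17 (SE). *POMC*, the precursor of α-MSH, ACTH and β-endorphin, differed by 1.28 ± 0.69 (SE; unadjusted p = 0.0962), or 0.67 without estradiol sulphate replicate 2, and *PCSK1*, which encodes a processing enzyme of its product, by 0.40 ± 0.38 (SE), or 0.16 without that replicate. The call was also lost without estradiol sulphate replicate 2 (adjusted p = 0.0664) or vehicle replicate 4 (adjusted p = 0.0637), with no filter (adjusted p = 0.0852) and with fry (adjusted p = 0.172).

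The wider list of hypothalamic neuropeptides and granins went both ways, 9 genes above and 7 below 0 out of 16 (adjusted p = 0.834). *GHRH*, the growth hormone releasing peptide, differed by 2.58 ± 0.94 (SE; adjusted p = 0.502) and was well above background in 4 treated and 2 control fetuses, with 2 treated fetuses above every control, and its difference ran from 1.83 to 3.14 over the alternatives (1.91 without estradiol sulphate replicate 2). *NPVF*, the precursor of gonadotropin-inhibitory RFamide peptides, differed by -1.21 ± 0.49 (SE; adjusted p = 0.536). Oxytocin (*OXT*) differed by -0.88 ± 0.47 (SE), or -0.45 without estradiol sulphate replicate 2, *GNRH1* by -1.59 ± 1.12 (SE) and the neurokinin B gene *TAC3* by 0.16 ± 0.56 (SE). *GNRH1* differed by -0.62 without estradiol sulphate replicate 1, by -0.85 without vehicle replicate 4 and by -2.32 without vehicle replicate 2. *TAC3* turned to -0.08 without estradiol sulphate replicate 2 and to -0.30 without vehicle replicate 2.

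**Figure D1:**
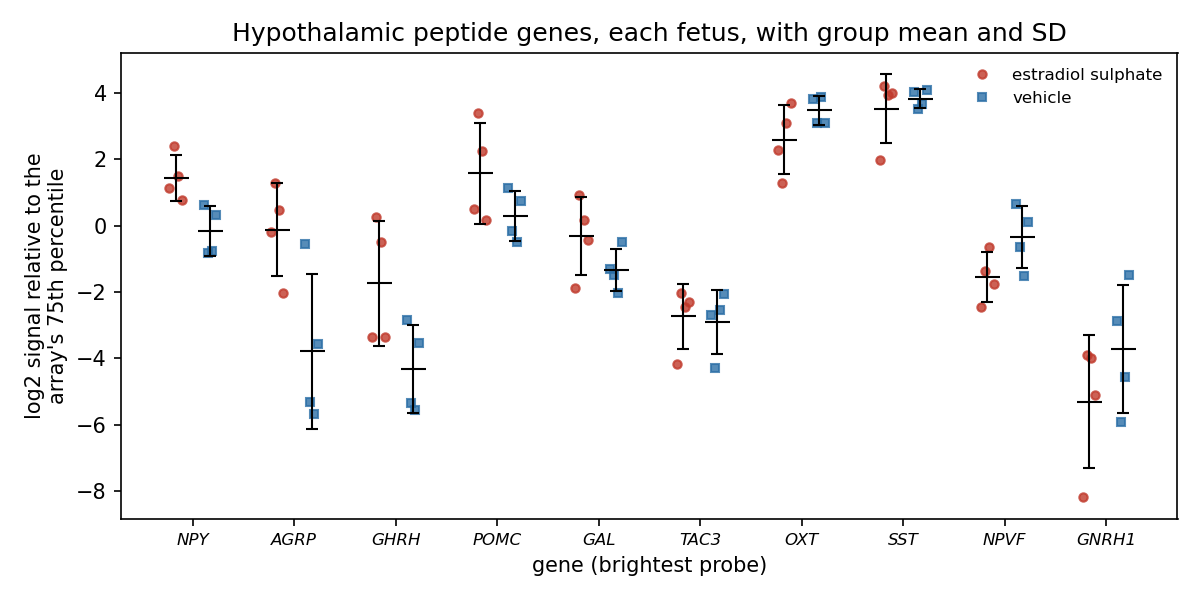
Log2 signal of 10 peptide genes relative to the array's 75th percentile (vertical axis) for each gene (horizontal axis), 1 point per fetus, with the group mean and SD as black bars. The 4 treated fetuses lie above all controls for NPY, while the groups overlap for AGRP, where 3 treated fetuses exceed every control.

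The reproductive list (12 genes, 10 above 0) did not pass (adjusted p = 0.675). *ESR1*, which encodes oestrogen receptor α, differed by 0.07 ± 0.47 (SE), and its other probe by -0.49. Its sign turned in 7 settings, in a range of -0.37 to 0.40. *ESR2*, which encodes oestrogen receptor β, differed by 0.42 ± 0.17 (SE; unadjusted p = 0.0376, adjusted p = 0.536). The progesterone receptor gene *PGR*, a classical oestrogen target, differed by 0.22 ± 0.17 (SE), a direction that turned with cyclic loess, and by 0.69 ± 0.15 (SE; adjusted p = 0.372) at its dimmer probe. That probe was well above background in 4 treated but 2 control fetuses, so its difference rests in part on values near background. The luteinizing hormone receptor gene *LHCGR*, well above background in 1 control fetus, differed by 0.56 ± 0.30 (SE). It differed by 0.10 with normexp and quantile and by 0.30 without vehicle replicate 2. Of 14 oestrogen-responsive genes 10 were above 0 (adjusted p = 0.834), led by *VEGFA* at 0.60 ± 0.26 (SE; unadjusted p = 0.0462) and *OXT* at -0.88. Aromatase (*CYP19A1*) was well above background on 1 array and the glucocorticoid receptor gene *NR3C1* on 2, so neither was tested. Among key genes, *STS*, *SULT1E1*, *CRH*, *AVP*, *CARTPT*, *PCSK2*, *KISS1* and *TH* were not analysed here, since no probe carried their names.

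Steroid sulphate handling (5 genes) did not pass (adjusted p = 0.943), with *ABCG2*, an exporter of sulphated steroids, at -0.31 ± 0.18 (SE) and the prostaglandin transporter gene *SLCO2A1* at 0.50 ± 0.32 (SE), or 0.22 without vehicle replicate 4. The stress axis list had 3 of 9 genes above 0 (adjusted p = 0.789), with *CRHR1* at 0.48 ± 0.26 (SE), or 0.21 without vehicle replicate 4, the cortisone reductase gene *HSD11B1* at -0.40 ± 0.25 (SE), and the mineralocorticoid receptor gene *NR3C2* at -0.02 ± 0.23 (SE) and 0.13 at its other probe. In the prostaglandin list (10 genes, adjusted p = 0.837), *PTGDS* differed by -0.35 ± 0.15 (SE; unadjusted p = 0.0391) and *PTGER4* by 1.20 ± 0.57 (SE), with 0.15 to 1.60 at its other probes. The cyclooxygenase genes *PTGS1* and *PTGS2* differed by -0.04 ± 0.33 and 0.39 ± 0.42 (SE). The test ranks a list against all other probes, and for the stress axis, heat shock, apoptosis and microglia lists it pointed down while the mean lay above 0. For the reproductive list it pointed up, with a median of 0.16 and a mean of -0.0028. No member of any list passed over all probes in limma, and adjusted over the list alone members passed in the appetite, inflammation, endothelial and matrix lists and, for *LEF1*, in the untested list of cortex and striatum markers.

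GABA and glutamate signalling had 14 measured genes, 13 above 0, with a median difference of 0.33 (camera, adjusted p = 0.00449), a call lost with an estimated correlation (adjusted p = 0.442). All 14 were glutamate receptors, glutamate transporters or glutamate dehydrogenase, and no gene of GABA signalling was measured. None passed over all probes or over the list alone. The AMPA receptor subunit *GRIA4* differed by 0.35 ± 0.13 (SE; unadjusted p = 0.0236), with 4 treated fetuses above every control. The NMDA receptor subunit *GRIN1* differed by 0.59 ± 0.23 (SE), the metabotropic receptor *GRM8* by 0.43 ± 0.19 (SE) and the glial glutamate transporter *SLC1A2* by 0.63 ± 0.24 (SE). With normexp and quantile *GRIA4*, *GRIN1*, *GRM8* and *SLC1A2* differed by 0.17, 0.30, 0.13 and 0.40. The call was also lost without estradiol sulphate replicate 2 (adjusted p = 0.0664) and with fry (adjusted p = 0.0695). Monoamine and acetylcholine genes (5, all above 0, adjusted p = 0.493) included the muscarinic receptor *CHRM3* at 0.39 ± 0.15 (SE) and the adrenergic receptor *ADRB1* at 0.25 ± 0.14 (SE). With normexp and quantile these 2 genes differed by 0.13 and -0.04. Each was well above background in 1 control fetus. Immediate early genes (10, 8 above 0, adjusted p = 0.317) included *CTGF* at 0.65 ± 0.27 (SE) and *JUNB* at 0.32 ± 0.14 (SE), which were 0.40 and 0.21 without estradiol sulphate replicate 1.

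**Figure D2:**
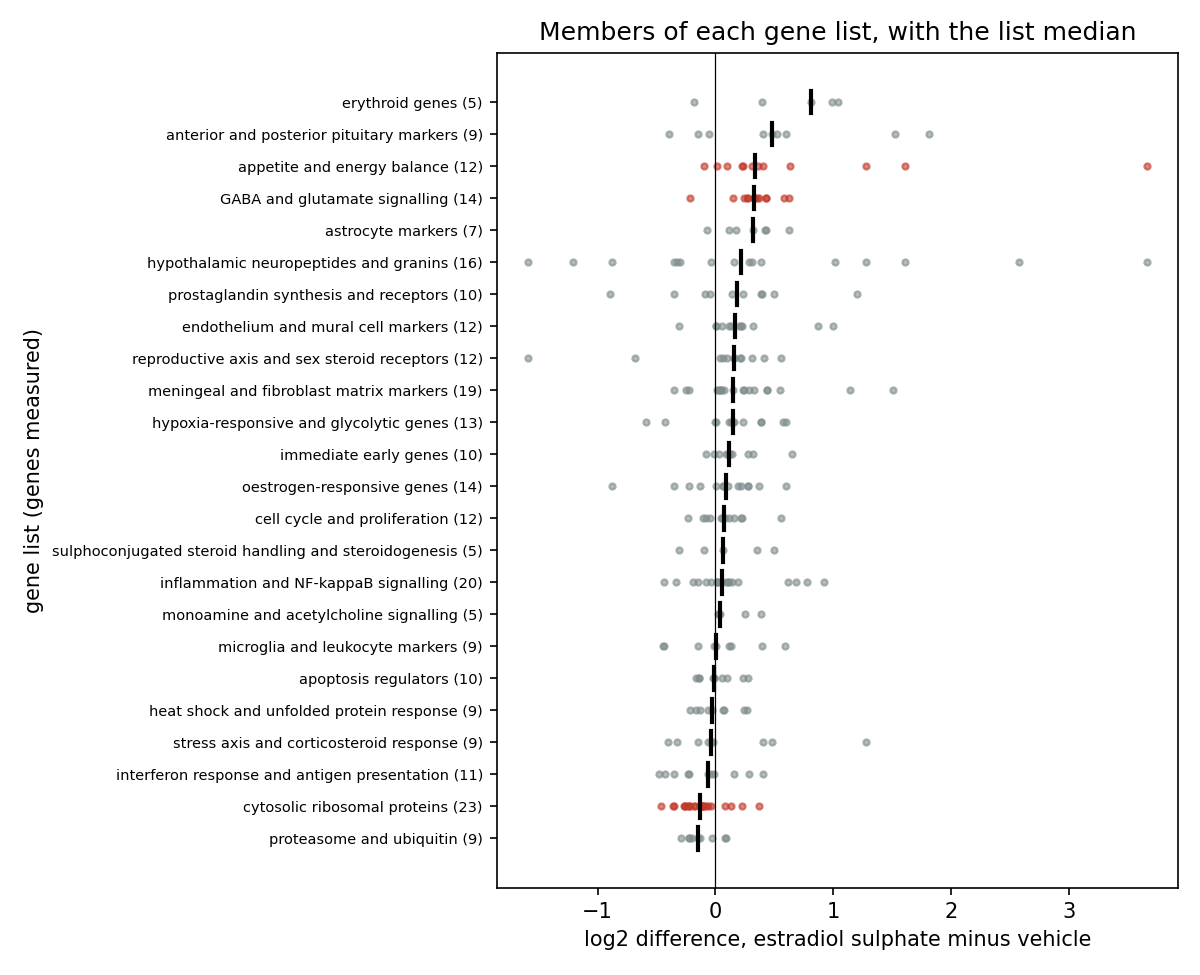
Log2 difference, estradiol sulphate minus vehicle (horizontal axis), of each measured gene (points) in the 24 tested lists (vertical axis, number of genes in brackets), with list medians as black bars. Red marks the 3 lists past the threshold with camera's preset correlation, with medians of 0.33, 0.33 and -0.13.

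Of 23 ribosomal protein genes, 19 were below 0, with a median of -0.13 (camera, adjusted p = 0.00106), a call lost with an estimated correlation (adjusted p = 0.442). *RPS25* differed by -0.47 ± 0.12 (SE; adjusted p = 0.427) at its brightest probe, by -0.15 at its other bright probe and by 0.44 and 0.69 at its 2 dim probes. *RPL6* differed by -0.36 ± 0.16 (SE) and *RPS12* by -0.35 ± 0.19 (SE), or by -0.23 and -0.17 without vehicle replicate 4. The list turned upwards with quantile normalization (median 0.06, adjusted p = 0.708), normexp and quantile (0.04, adjusted p = 0.548) and cyclic loess (0.06, adjusted p = 0.538). The call was also lost without vehicle replicate 4 (adjusted p = 0.0713) and with fry (adjusted p = 0.328). Proteasome and ubiquitin genes (9, 7 below 0) had a median of -0.15 (adjusted p = 0.0584) and passed in camera with a trended prior (adjusted p = 0.0423), with values up to 0.851 in the other alternatives. With fry, which does not compare a list with other genes, it had an adjusted p of 0.00455, while the brightest probes as a whole had a median of -0.12. The ubiquitin gene *UBB* differed by -0.29 ± 0.12 (SE), a sign that turned with quantile, normexp and cyclic loess, and *PSMA6* by -0.22 ± 0.12 (SE).

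Direction followed signal. Among the 2347 dimmest probes the median difference was 0.20, with 360 probes higher and 10 lower at an unadjusted p under 0.05. Among the 2347 brightest it was -0.12, with 22 higher and 235 lower. With quantile normalization the same bins had medians of 0.02 and -0.01. A dim probe could pass the filter through the 4 treated arrays alone, which had more probes well above background. With probes above background on all 8 arrays, 476 were higher and 367 lower, and with no filter 904 and 1186. How much the filter adds to the rise among dim probes was not tested. Ribosomal protein genes lay among the bright probes, with a mean log2 signal of 4.47, and the 2 raised lists lay at -2.15 and -1.79.

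**Figure D3:**
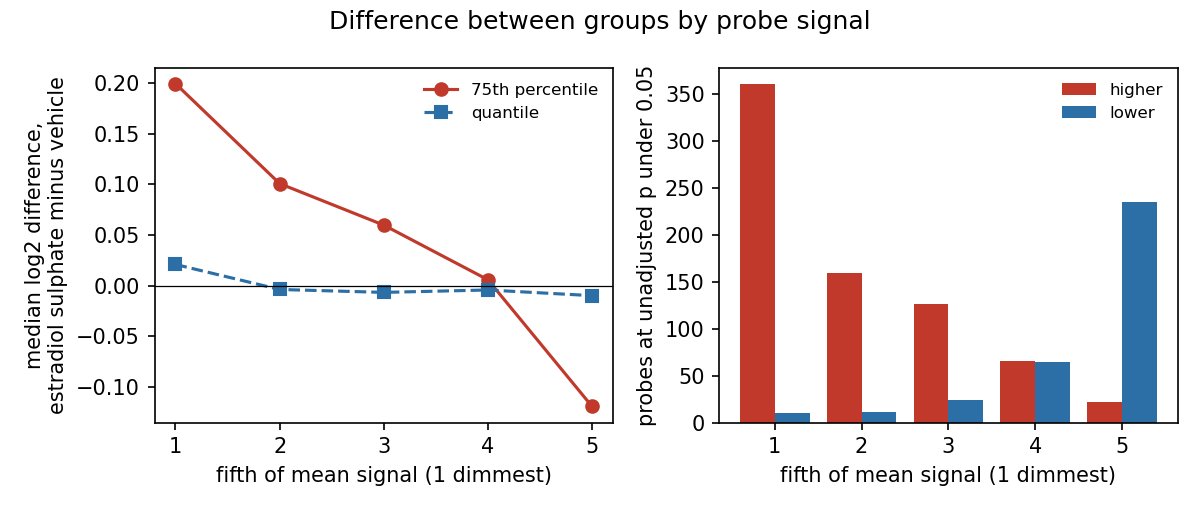
Left, median log2 difference (estradiol sulphate minus vehicle) in 5 bins of 2347 probes by mean signal, with the 75th percentile scaling (red) and quantile normalization (blue). Right, number of probes at an unadjusted p under 0.05 per bin with the 75th percentile scaling. Dim probes were mostly higher (360 against 10) and bright probes mostly lower (22 against 235).

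Hypoxia-responsive and glycolytic genes had 11 of 13 members above 0 and a median of 0.15, short of the threshold (adjusted p = 0.206). The list passed with quantile normalization (adjusted p = 0.0107), normexp and quantile (0.0246), cyclic loess (0.0115) with probes above background on all arrays (0.0313) and without estradiol sulphate replicate 4 (0.0478), in a range of 0.0107 to 0.512. Its leading members were the lactate transporter *SLC16A1* at 0.39 ± 0.14 (SE), hexokinase (*HK1*) at 0.57 ± 0.22 (SE), *VEGFA* and *LDHA* at 0.39 ± 0.20 (SE), or 0.20 without estradiol sulphate replicate 1. Heat shock (9 genes, adjusted p = 0.969), cell cycle (12, adjusted p = 0.837) and apoptosis genes (10, adjusted p = 0.837) did not pass. In these lists the chaperone *HSPA5* differed by 0.27 ± 0.12 (SE) and *ATF4* by 0.25 ± 0.13 (SE). The cell cycle genes *CCND2* and *CDKN1C* differed by 0.56 ± 0.21 and 0.16 ± 0.13 (SE), and the apoptosis regulators *BCL2* and *BCL2L1* by 0.27 ± 0.17 and 0.23 ± 0.16 (SE).

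Markers of other cell types were not shifted past the threshold. Astrocyte markers (7 genes) had a median of 0.32 (adjusted p = 0.273) and passed with quantile normalization (adjusted p = 0.0431), normexp (0.0246) and cyclic loess (0.0212), in a range up to 0.573. *SLC1A2* and *SLC1A3*, the latter at 0.43 ± 0.25 (SE), belong to this list and to the glutamate list. Meningeal and fibroblast matrix genes had 16 of 19 members above 0 (adjusted p = 0.143; 0.0440 without estradiol sulphate replicate 4, up to 0.523). The probe of the collagen gene *COL6A1* was not well above background in any control fetus. It was at least 1.72-fold brighter after estradiol sulphate with the 75th percentile scaling (adjusted p = 0.372). With normexp and quantile its log2 difference was 0.26, a size set in part by background. The brightest probe of *COL3A1* was likewise at least 1.33-fold brighter (adjusted p = 0.515), while its other probes, each well above background in 1 control fetus, differed by 0.33 and 0.20, and with normexp and quantile the brightest differed by 0.10. *COL4A1* differed by 0.33 ± 0.12 (SE) and *TIMP3* by 0.55 ± 0.22 (SE), or by 0.01 and 0.27 with normexp and quantile. Endothelial markers had 11 of 12 above 0 (adjusted p = 0.287; 0.0434 without vehicle replicate 3, up to 0.927). The brightest probe of the VEGF receptor *FLT1*, well above background in no control fetus, was at least 2.00-fold brighter with the 75th percentile scaling (adjusted p = 0.427), with a log2 difference of 0.36 after normexp and quantile. Its other probe, well above background in 1 control fetus, differed by 0.64. Endothelin (*EDN1*) differed by 0.87 ± 0.32 (SE). *COL6A1* and *FLT1* each passed when adjusted over the list alone.

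Microglia and leukocyte markers (9 genes, median 0.00, adjusted p = 0.837) included *FCER1G* at -0.44 ± 0.20 (SE) and *CYBB* at 0.59 ± 0.33 (SE), or 0.33 without estradiol sulphate replicate 2. Inflammation genes (20, adjusted p = 0.675) included *IL13RA1*, which passed over the list alone, and *NFKBIA* at 0.68 ± 0.24 (SE), or 0.42 without estradiol sulphate replicate 1. Interferon and antigen presentation genes (11, 3 above and 8 below 0, adjusted p = 0.778) included *IRF2* at 0.41 ± 0.15 (SE), or -0.0032 with normexp and quantile, and *IRF3* at 0.29 ± 0.15 (SE). In the same list *MX2* differed by -0.35 ± 0.19 (SE) and *MX1* by -0.48 ± 0.33 (SE). Erythroid genes (5, adjusted p = 0.675) included *HBB* at 0.40 ± 0.53 (SE) and fetal haemoglobin (*HBF*) at 1.04 ± 0.57 (SE), or 0.27 with normexp and quantile. Pituitary markers (9, adjusted p = 0.675) included *GHRHR* at 0.41 ± 0.21 (SE), or -0.03 with normexp and quantile, *CRHR1*, prolactin (*PRL*) at -0.40 ± 0.24 (SE), with -0.97 at its other probe, and the glycoprotein hormone subunit gene *CGA* at 1.82 ± 1.37 (SE), with 2.36 at its other probe. Transthyretin (*TTR*), abundant in choroid plexus, differed by 0.89 ± 1.00 (SE), with an SD of 2.47 in the treated and 0.21 in the control fetuses. The *TTR* difference was 2.02 without estradiol sulphate replicate 1 and 0.09 without replicate 4 of that group. Too few genes were measured for tests of the respiratory chain (2), synaptic markers (3), oligodendrocyte markers (3), ependyma and choroid plexus (3), cortex and striatum markers (2) and hypothalamic identity factors (2), which had medians of -0.16, -0.14, -0.03, -0.07, 0.22 and 0.23.

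Among named genes at their brightest probe, 61 were higher and 22 lower at an unadjusted p under 0.05, and none passed after adjustment. By unadjusted p the 12 highest-ranked of the first kind were *LEF1*, *TIMELESS*, *COL6A1*, *FTO*, *DERL1*, *CSNK1E*, *IL13RA1*, *NPY*, *SERPINF1*, *FLT1*, *SCNN1A* and *FGFR2*, all with 4 treated fetuses above every control. They were picked for a small p on these same arrays, so this separation adds no support. *SERPINF1*, *SCNN1A* and *FGFR2* were well above background in all 4 treated fetuses but in 2, 1 and 2 control fetuses. *LEF1*, a transcription factor of Wnt signalling, was 2.14-fold brighter (unadjusted p = 4.48e-05) and was well above background in 1 control fetus. Its log2 difference was 0.40 with normexp and quantile. The other *LEF1* probe gave 1.09. *TIMELESS*, of the clock and replication machinery, differed by 1.02 ± 0.18 (SE; adjusted p = 0.308). *CSNK1E*, a kinase of clock proteins, differed by 0.62 ± 0.15 (SE; adjusted p = 0.385). *IL13RA1* differed by 0.93 ± 0.22 (SE; adjusted p = 0.404). *DERL1*, *SERPINF1*, *SCNN1A* and *FGFR2* had differences of 0.55, 0.93, 0.50 and 0.50, or 0.45, 0.47, 0.10 and 0.20 with normexp and quantile. In that setting *TIMELESS*, *CSNK1E* and *IL13RA1* differed by 0.55, 0.34 and 0.47.

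Lower genes ranked the same way included *NUDT16*, *RPS25*, *CHID1*, *FABP5*, *SFTPC*, *LGALS15*, *ASIP*, *CENP-B*, *MUC2*, *LPAAT* and *ALB*, with differences from -0.92 to -0.31. *NUDT16*, which encodes a hydrolase of RNA caps and inosine nucleotides, differed by -0.92 ± 0.23 (SE; adjusted p = 0.427), and its other probe by -0.93. *FABP5*, a fatty acid binding protein, differed by -0.44 ± 0.14 (SE; adjusted p = 0.453). The probes of *MUC2*, like those of *RPS25*, disagreed in sign. Among 88 genes followed through the alternatives, the log2 difference of 52 was smaller by over 1.5 times with normexp and quantile, where an offset of 50 is added to intensities. That of 41 moved by over 1.5 times or turned when 1 array was left out. In simulated data of this size, with independent noise and 200 changed probes, 80.0% of changes of 1 on the log2 scale were recovered but 2.0% of changes of 0.5. These shares need not hold for the real arrays, where *NPY* at 1.61 did not pass.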

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

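The search for probes that the filter left out was chosen after the values were seen, and the screen for single fetuses before. Among 192 groups of 4 fetuses looked at, over genes named in the text and array measures, 11 held a fetus whose gap to the others exceeded Dixon's critical value for 4 values, where chance gives about 10 (1 in 20). Of these, 5 fell on vehicle replicate 4. It lay at 50.3 on the first principal component against -18.5 to -8.58 for the other controls. On the log2 scale relative to the 75th percentile it had *COL6A1* at -6.93 (others -6.32 to -6.25), *VEGFA* at -0.82 (others -1.67 to -1.54), *RPS12* at 7.67 (others 6.91 to 6.99) and *FCER1G* at 0.97 (others 0.29 to 0.40). *COL6A1* was not well above background in any control, so its gap lies between values near background. *FCER1G* was also highest in replicate 4 of the treated group (0.49, others -0.17 to 0.08). Vehicle replicate 4 also had the lowest signal and the lowest array weight, 0.271. Without it the count of probes at an unadjusted p under 0.05 was 919 higher and 372 lower, and none passed after adjustment.

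The other cases fell on other fetuses. Estradiol sulphate replicate 1 had *SST* at 1.98 against 3.92 to 4.21 in the other treated fetuses. Replicate 2 of that group had *FABP5* at 3.79 (others 4.22 to 4.27) and replicate 3 had *SFTPC* at 1.48 (others 1.40 to 1.40). Among controls, replicate 1 had *DERL1* at -2.09 (others -1.99 to -1.97), replicate 2 had *COL3A1* at -6.12 (others -5.55 to -5.50) and replicate 3 had *NFKBIA* at 0.073 (others -0.25 to -0.23).

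A probe that the filter left out, A_70_P066011, which carries no gene name, was well above background in 3 treated fetuses and in no control. Its values parted by 7.71 on the log2 scale, a size set at its lower end by background. Estradiol sulphate replicates 2, 3 and 4 lay at 0.97, 0.86 and 0.80, and replicate 1 lay at -8.05, with the controls at -7.81 to -6.91.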

How the results depend on the processing

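Cyclic loess normalization was chosen after seeing the data, and all other settings before. No probe passed the adjusted threshold with limma in any of the 19 settings, and smallest adjusted p-values ran from 0.0859 (array weights) to 0.768. Probes higher at an unadjusted p under 0.05, 733 as reported, numbered 396 with quantile normalization, 422 with normexp and quantile, 344 with the deposited log2 values, 476 with probes above background on all 8 arrays, 1115 with array weights, 448 with cyclic loess, and 474 (without vehicle replicate 2) to 919 with 1 array left out. Probes lower, 344 as reported, numbered 760 with the deposited values, 1186 with no filter (904 higher), and 178 (without estradiol sulphate replicate 2) to 372 with 1 array left out. The filters change which probes are tested (10001 and 15008 in number). Those added with no filter were well above background on fewer than 4 arrays. The deposited values change the centring. With quantile normalization the dimmest 2347 probes went from 360 higher and 10 lower to 122 and 59. The brightest 2347 went from 22 and 235 to 80 and 61. For the other settings the cause was not tested.

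Of 24 lists, 3 passed with the preset correlation, 0 with an estimated correlation and 1 with fry, which tests a list against no change, namely the proteasome list (adjusted p = 0.00455), and 1 (without estradiol sulphate replicate 2 or vehicle replicate 4) to 5 with 1 array left out. Appetite and energy balance had an adjusted p of 0.00930 as reported, 0.0852 with no filter, 0.442 with an estimated correlation, 0.172 with fry, and 0.000890 to 0.0664 with 1 array left out. GABA and glutamate signalling had 0.00449 as reported, 0.442 with an estimated correlation, 0.0695 with fry, and 0.000704 to 0.0664 with 1 array left out. Ribosomal proteins had 0.00106 as reported, 0.442 with an estimated correlation, 0.328 with fry, and 9.40e-05 to 0.0713 with 1 array left out. They turned upwards with quantile normalization (0.708), normexp and quantile (0.548) and cyclic loess (0.538). Of the 24 lists, 10 kept 1 direction throughout. The causes were not tested here, apart from signal, which is weighed among the other observations.

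Of 88 genes, 77 kept their sign in every setting, including 45 of the 48 at an unadjusted p under 0.05. The other 3 turned. *RPS25* was 0.13 as the mean of its probes. *UBB* was 0.038 with quantile normalization, 0.029 with normexp and quantile and 0.018 with cyclic loess. *IRF2* was -0.0032 with normexp and quantile. The cause was not tested.

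The replicate number as a block gave 0 probes past the adjusted threshold, 804 higher and 354 lower at an unadjusted p as a fixed block, and 848 and 426 as a random block (correlation 0.112), with 3 lists passing each time. Same-numbered fetuses deviated together in 3 of 4 pairs (correlations -0.01 to 0.25), and 6 of 8 arrays correlated best with their own number. The labels do not say that a number marks a twin set, so no pairing was assumed in the main model. Equal numbers also share a slide row. A slide or scan block could not be fitted, since there was 1 of each. Signal over background limits the dim probes, of which 3259 were left out.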

Other observations

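The tests on arcuate tissue and on vehicle replicate 4 were chosen after the result was seen, as was the search for probes present in some fetuses alone. In that search, 7 probes were well above background in 2 to 6 fetuses and at background in the rest, with a gap over 3 on the log2 scale. Of these, 1 is named, *OVAR-DQA1*, a class II histocompatibility gene. It was at background in vehicle replicates 3 and 4 (-7.60 and -6.97) and between -3.50 and -0.17 in the other 6 fetuses. 2 of the 7 were above background in 1 group alone. Hormone genes of the pars tuberalis and pituitary also varied within groups. *CGA* ran from -4.55 to 0.55 in the treated and from -5.46 to -0.34 in the control fetuses, and *TSHB* from -8.12 to -1.84 and from -7.52 to -2.82.

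*NPY*, *AGRP* and *GHRH* together were brighter by a mean of 2.62 (SE 0.96) after estradiol sulphate, and were put together for their high values, so no p is given for them. The trend with signal over all probes, with bin medians from -0.12 to 0.20, is too small to give this. Removing it by cyclic loess left 2.55 (SE 0.97). Cyclic loess does not address controls in which *AGRP* and *GHRH* were not well above background, 2 of 4 for each gene. Array brightness therefore stays open for these 2 genes. With normexp and quantile *AGRP* differed by 2.62, *GHRH* by 1.83 and *NPY* by 1.54. A candidate explanation is that the treated pieces held more of the arcuate nucleus. The other measured arcuate peptides, *POMC*, *GAL* and *TAC3*, differed by a mean of 0.82 (exact permutation p = 0.286), *CGA* and *TSHB* of the neighbouring pars tuberalis by 1.67 (exact permutation p = 0.257), and 5 peptides of other nuclei (*OXT*, *SST*, *PMCH*, *NPVF*, *GNRH1*) by -0.73 (exact permutation p = 0.286), which leaves this open. Within groups, the mean of *NPY*, *AGRP* and *GHRH* and that of *POMC*, *GAL* and *TAC3* were highest in the same fetuses. These were estradiol sulphate replicates 2 and 3, at 1.31 and 0.49 and at 0.75 and -0.01. Among controls they were replicates 1 and 4, at -0.93 and -2.26 and at -0.96 and -0.61. Variation among fetuses of the same group is not a difference between treatment and control, and its source was not tested. An effect of the estradiol sulphate infusion also stays open, and with 4 fetuses per group it cannot be told apart from more arcuate tissue.

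Probes of low signal were mostly higher and probes of high signal mostly lower after estradiol sulphate. All 4 treated arrays had a slope of log2 signal on mean signal of -0.0292 to -0.00906, and the controls -0.00193 to 0.0556. Brighter arrays could give this. Within the groups, slope and brightness correlated at r = -0.42 (exact permutation p = 0.464) and rho = -0.17 (exact permutation p = 0.752) over 8 arrays, and at r = 0.35 without the 2 farthest from the median, so the arrays are too few to decide. Treated and control arrays also lay in separate columns of the slide, so a column effect cannot be told apart from the treatment.

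The ribosomal protein genes had a median of -0.13. Among 10000 random lists matched on mean signal, drawn from 50 probes on each side, the median was -0.21 and the central range -0.28 to -0.12, which puts the list at the 96.7th percentile. Its shift may therefore come from the trend with signal alone, in line with the turn under cyclic loess. Vehicle replicate 4 as the source stays open, since without it the median was -0.11 but the mean moved from -0.13 to -0.06 and the call was lost (adjusted p = 0.0713). Against random lists matched in the same way, the GABA and glutamate list (0.33 against -0.04 to 0.21) and the appetite list (0.33 against -0.06 to 0.18) lay higher, though these lists ignore correlation between genes.

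The 8 arrays split into 4 and 4 in 35 ways. For probes past the adjusted threshold in limma, the real count of 0 leaves nothing to test, since all 35 splits give at least that many, with up to 4 in the others. For probes at an unadjusted p under 0.05, 3 splits, the real one among them, gave at least 1077, so chance cannot be excluded. The highest other, 1303, set estradiol sulphate replicate 1 with vehicle replicates 1, 2 and 3. The next, 1227, set estradiol sulphate replicates 1 and 4 with vehicle replicates 1 and 3. Both kept the same-numbered replicates 1 on the same side. Among the splits that part every same-numbered pair, the real one had the most, with 839 next, but these are too few to exclude chance. For lists, 12 splits, the real one among them, gave at least the real 3, with 6 as the highest other, so chance cannot be excluded there either.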
